A study of Mus musculus with 2 samples.

How the data were processed

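Total RNA from neonatal mouse epidermis was measured by RNA-seq in 2 libraries, 1 from wild-type C57BL/6 animals (WT) and 1 from C57BL/6 animals homozygous for the Foxn1 allele L19M. The labels' protocols describe TRIzol extraction, poly(A) selection and a directional (strand-marking) library kit. The number, age in days and sex of the pups behind each library are not given in the sources used here. Genotypes were taken from the labels alone. With 1 library per genotype there is no replicate, so no test between genotypes was run and no p-value is given. Every difference compares these 2 libraries, has no replicate check, and may hold variation in age or sex, or between litters or preparations.

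The deposited table has 1 row for each of 23183 genes with a unique symbol. Its columns headed as raw data hold FPKM, fragments scaled by transcript length and by the library total, for each library, as the authors computed them. Cufflinks, edgeR and R 3.5.1 are named, with no role, per the submitters' processing notes; the aligner is not given in the sources used here. The authors also deposited log2 values, headed as normalized, which lay within 0.0476 of log2(FPKM + 1) in every row, and per the file headers and information sheet, by quantile normalization the pair of libraries had been given a common distribution. The authors' deposited fold was the ratio of L19M over WT from those normalized values. Transcript lengths came from the same deposited table. The information sheet gives the genome build as mm10, while the submitters' processing notes list GRCm39. Of 21982 symbols shared with the RefSeq annotation of GRCm38 (the same assembly as mm10), 95.5% started within 5000 bases of its gene start, so coordinates are given as mm10, counted from 1. Whether fragments were counted by strand, and how fragments shared between genes were divided, is not given in the sources used here. Values of near-identical gene family members (Sprr2, Lce, Krtap, stefins) and of overlapping genes are therefore uncertain singly. Sums are given for the Sprr2, Lce1, Lce3 and Krtap families.

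The planned analysis allowed for counts or normalized values, and the rule for normalized values applied. For each gene the log2 ratio of L19M over WT was computed as log2((FPKM in L19M + 1)/(FPKM in WT + 1)). The pseudocount of 1 understates the difference of genes with low FPKM. A gene counted as measured when its mean FPKM over both libraries was at least 1, and was called higher or lower when measured and at least 2-fold apart on that scale. Foxn1, Wnt5a and Wnt5b were named whatever their values. Also named were the 15 measured genes with the largest and the 15 with the smallest log2 ratio, and the 4 measured members of each gene list with the largest absolute log2 ratio. Symbols of predicted genes (Gm and a digit, Rik, LOC), microRNAs, small nuclear and nucleolar RNAs (with guide RNAs), ribosomal RNAs, antigen receptor segments and pseudogenes were passed over in the ranking. The ranking, the thresholds and 34 gene lists with 892 entries were fixed before the data were examined. The lists cover epidermal layers, hair follicle, secreted signals, pathways, other cell types of skin and sample handling. Of the entries, 24 matched no row and are not analysed here, among them the whole mitochondrially encoded list. Each list has its counts of called genes, its median log2 ratio, and the percentile of that median among 10000 random lists of the same size drawn from measured genes in the same 20 bins of mean FPKM. The percentile describes these libraries and is not a test. A few genes that this rule names are not reported here. Further genes and lists that were chosen after their values were seen are named as such.

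Low FPKM values of long transcripts stepped as whole fragments, each worth 1 fragment divided by the library's total and by the transcript length less a constant. Fitting that relation gave 14163398 fragments for WT with a constant of 207 bases and 19228032 for L19M with 211 bases. With transcripts of at least 1000 bases and values of up to 20 fragments, 84.0% of values in WT and 83.4% in L19M came out within 0.1 of a whole number. Fragments per gene were estimated from this for transcripts of at least 300 bases. They give exact 95% intervals for single FPKM values (Poisson) and for FPKM ratios (Clopper-Pearson). These intervals cover counting error only, since fragments copied by PCR are not independent molecules and the spread between animals is not in them. A count of 0 allows up to 3 fragments, which for a transcript of 2000 bases is 0.118 FPKM in WT and 0.0872 FPKM in L19M.

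The procedure was tested on simulated libraries with sampling noise only, drawn from the real mean FPKM and fitted depths, with 200 genes changed by known folds. Among 11644 measured genes it called 100% of the genes changed 3-fold and 100% of those changed 6-fold in the right direction. It also called 1 unchanged gene. The changed genes were drawn from longer transcripts with a mean of at least 4 FPKM. Recovery of changed genes nearer the 1 FPKM floor was therefore not simulated. The fitted depth was 100% of the depth set in either library, and 95.4% of the ratio intervals of 1000 unchanged genes held the true ratio. Both results follow largely by construction. Whole fragments were drawn by the same relation that was then fitted, and the intervals used the set depth. Fragments shared between genes were not simulated, so the intervals of near-identical genes were not checked. Alternatives were pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5 FPKM, centring on the median ratio, library sizes without the 20 most abundant genes, the authors' quantile-normalized values, and 1.5-fold and 4-fold rules. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.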

Results

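The data comprised poly(A)-selected RNA-seq of neonatal mouse epidermis, with 1 WT library and 1 library from animals homozygous for Foxn1 L19M. Foxn1 encodes a forkhead transcription factor of keratinocytes and thymic epithelium whose loss gives the nude mouse. The design asked how keratinocyte function differs between these genotypes, and the series title concerns a Wnt ligand of keratinocytes and the formation of fat cells in the dermis. Depth was estimated at 14163398 fragments for WT and 19228032 for L19M. FPKM was above 0 for 16481 genes in WT and 16670 in L19M, and the 20 most abundant genes held 24.4% and 24.2% of the FPKM total. Differences are given as L19M over WT, and none has a replicate check.

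Foxn1 RNA was higher in the L19M library, and RNA of both Wnt5 ligands was lower, all short of the 2-fold rule. Foxn1 (Entrez 15218, minus strand of chromosome 11, 78357577 to 78386608, mm10) had 3.74 FPKM in WT and 5.44 FPKM in L19M. Its FPKM ratio was 1.45, with a counting interval of 1.20 to 1.77, and its log2 ratio was 0.44. RNA level does not check the genotype of an allele named for an amino acid replacement. Wnt5a (Entrez 22418, plus strand of chromosome 14, 28505473 to 28525515) had 2.05 FPKM in WT and 1.04 FPKM in L19M, a ratio of 0.506 with an interval of 0.378 to 0.674. Wnt5b (Entrez 22419, minus strand of chromosome 6, 119432531 to 119544347) had 1.21 FPKM in WT and 0.698 FPKM in L19M. Its ratio was 0.579 with an interval of 0.356 to 0.937, from 42 estimated fragments in WT and 33 in L19M. Its mean lay below the 1 FPKM floor for a measured gene. On the log2 scale with the pseudocount, the differences were -0.58 for Wnt5a and -0.38 for Wnt5b.

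Among the 11 measured Wnt ligands, Wnt11 alone met the 2-fold rule. It was lower in L19M, at 1.39 FPKM against 4.38 FPKM, a ratio of 0.317 with an interval of 0.243 to 0.412. Wnt10b was the ligand with the largest positive log2 ratio (0.67), at 9.93 FPKM in WT and 16.4 FPKM in L19M, and Wnt3a had 2.28 FPKM in WT and 1.49 FPKM in L19M. The most abundant ligands, Wnt7b (61.3 and 63.1 FPKM) and Wnt4 (46.4 and 53.0 FPKM), had ratios of 1.03 and 1.14. The median log2 ratio of the ligands was 0.03 and their mean -0.10, opposite in sign, and the median lay at percentile 64.2 of matched random lists. None of 31 measured Wnt receptors and modulators met the rule, and their median of 0.04 (percentile 65.2) changed sign under other settings. The members furthest from equality were Nkd2 (-0.89), Dkk4 (0.72), Fzd5 (-0.68) and Dkk3 (0.50). None of 17 measured targets of beta-catenin signalling met it either. Their median log2 ratio was 0.12, at percentile 92.9, with Lef1 at 0.87 and Sp5 at 0.46 beside Nkd2 and Dkk4.

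**Figure D1:**
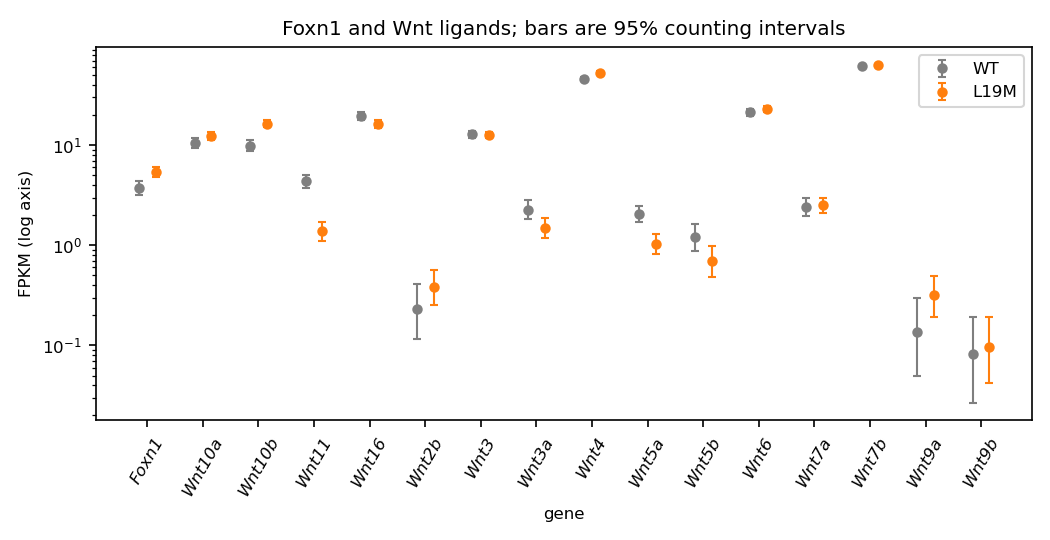
FPKM on a log axis of Foxn1 and of the Wnt ligands with at least 5 estimated fragments in each library, in the WT library (grey) and the L19M library (orange). Bars are 95% Poisson counting intervals and hold no variation between animals. Wnt11 shows the widest gap between libraries among measured ligands, 4.38 against 1.39 FPKM, and Wnt5a and Wnt5b lie lower in L19M.

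Of 11841 measured genes, 63 (0.532%) were at least 2-fold higher in L19M and 203 (1.71%) at least 2-fold lower. Of the higher genes 21 were in the list of stress keratins, alarmins and epidermal inflammation, and of the lower genes 63 were in the hair shaft list or the keratin-associated protein (Krtap) family. At 4-fold the counts were 29 higher and 85 lower. The other 11575 measured genes were under 2-fold. The median log2 ratio of measured genes was 0.0049 with quartiles of -0.17 and 0.16, and Pearson's r between the libraries' log2(FPKM + 1) was 0.971 across genes, which are not independent replicates. With a pseudocount of 0.1 there were 120 genes at least 2-fold higher in L19M and 297 genes at least 2-fold lower in L19M.

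**Figure D2:**
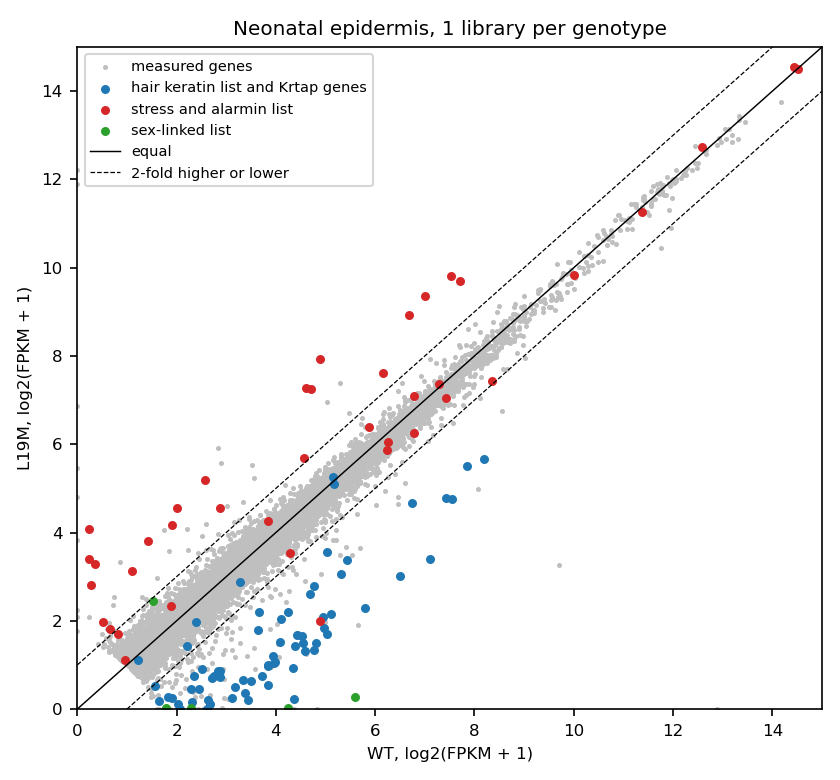
Expression of measured genes (mean of at least 1 FPKM) as log2(FPKM + 1) in the WT library (x axis) and the L19M library (y axis), 1 point per gene. The solid line marks equality and the dashed lines 2-fold. Hair keratin and Krtap genes (blue) lie mostly below the lower line, 63 of them 2-fold lower, and 21 genes of the stress and alarmin list (red) lie above the upper line.

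Genes of the hair shaft and inner root sheath, the hardening parts of the growing hair, were lower in L19M as a group. Of 31 measured members of that list, 25 were at least 2-fold lower and none higher, with a median log2 ratio of -2.13 at percentile 0 of random lists. The shaft keratins Krt33a (31.8 FPKM in WT, 2.27 FPKM in L19M), Krt31 (27.1 and 1.82 FPKM), Krt34 (19.8 and 1.68 FPKM) and Krt81 (14.5 and 1.05 FPKM) were furthest apart. The ratio for Krt31 was 0.0672, with a counting interval of 0.0489 to 0.0904. Keratin-associated proteins, which crosslink shaft keratins, were not a list of their own and were counted after their values were seen. All 38 measured Krtap genes were 2-fold lower, with log2 ratios from -4.14 to -1.04, and the FPKM sum over 53 Krtap genes was 695 in WT and 59.5 in L19M. Together the hair list and the Krtap genes made up 63 (31.0%) of the 203 lower genes.

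Krtap genes also took 10 of the ranks among the 15 smallest log2 ratios. Krtap8-1 had 137 FPKM in WT and 9.62 FPKM in L19M, Krtap7-1 had 89.5 and 7.11 FPKM, Krtap22-2 had 54.4 and 3.90 FPKM, and Krtap11-1 had 30.2 and 2.55 FPKM. Krtap9-3 had 26.3 and 1.52 FPKM, Krtap3-3 had 23.1 FPKM in WT and a ratio of 0.0648, Krtap6-5 had 19.4 and 0.911 FPKM, and Krtap1-4 had 13.4 and 0.453 FPKM. Krtap15 and Krtap14 had 2 estimated fragments each in L19M. Their ratios were 0.00853 (interval 0.00102 to 0.0313) and 0.0163 (0.00195 to 0.0606). Of 22 measured genes of the hair follicle epithelium list, 11 had log2 ratios above 0 and 11 below, and 1 was called lower, Krt79, a keratin of the upper follicle and sebaceous duct (517 FPKM in WT, 247 FPKM in L19M). The list's median was 0.07, at percentile 85.2, and changed sign under other settings. Lef1 (7.64 and 14.8 FPKM) had a positive log2 ratio and Foxe1 (2.10 and 0.632 FPKM) a negative one, both under 2-fold with the pseudocount. Genes of melanocytes, the pigment cells of skin and hair, had a median of -0.14 over 16 measured members (percentile 2.83). Tyrp1, a pigment enzyme, was the 1 called member, at 15.8 FPKM in WT and 5.08 FPKM in L19M. Pmel (-0.89), Dct (-0.62) and Sox10 (0.61) were under 2-fold.

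Genes of stress keratins, alarmins and antimicrobial proteins were mostly higher in L19M, with 31 measured members of their list above 0 and 9 below. Of 40 measured members of that list, 21 were at least 2-fold higher and 1 lower, with a median log2 ratio of 1.14 at percentile 100. Krt6b, a keratin of wounded and hyperproliferative epidermis (minus strand of chromosome 15, 101676023 to 101680289), had 128 FPKM in WT and 651 FPKM in L19M, a ratio of 5.09 with an interval of 4.92 to 5.27. S100a8 (25.1 and 151 FPKM) and S100a9 (23.2 and 154 FPKM), which form the alarmin calprotectin, had ratios of 6.00 (interval 4.63 to 7.87) and 6.61 (interval 5.41 to 8.21). Slpi, a secreted protease inhibitor, had 1.69 and 13.1 FPKM. The acute-phase genes Saa1 and Saa3, the beta-defensin Defb4 and Sprr2f had 1 estimated fragment each in WT. Their ratios were 90.9 (interval 16.0 to 3619), 27.6 (interval 4.66 to 1121), 31.4 (interval 5.35 to 1274) and 54.4 (interval 9.46 to 2177). Defb6, another beta-defensin and the 1 member called lower, was named after its values were seen, and had 28.5 FPKM in WT and 2.99 FPKM in L19M. Also given after their values were seen are Krt17 (1025 and 909 FPKM) and sums over the Serpinb3 genes (514 and 306 FPKM) and the Defb genes (208 and 237 FPKM). Among markers of other cells, the mast cell and granulocyte list had a median of 0.55 over 7 measured genes (percentile 100). Its 1 called gene was Hdc, the histamine-forming enzyme (2.03 and 6.78 FPKM). Cxcr2 had 0.871 and 1.89 FPKM, Kit 2.66 and 4.40 FPKM, and the mast cell protease Mcpt4 24.2 and 15.6 FPKM.

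In the epidermal differentiation complex on chromosome 3, 7 of 9 measured Sprr2 genes and 5 of 6 Lce3 genes were at least 2-fold higher. Sprr2d (92339140 to 92340873) had 28.6 FPKM in WT and 244 FPKM in L19M, Sprr2e 3.05 and 22.6 FPKM, and Sprr2g 4.93 and 35.3 FPKM. Over all 12 Sprr2 genes, which are near-identical in sequence, the FPKM sum was 130 in WT and 568 in L19M, a ratio of 4.36. In the granular layer and cornified envelope list, 7 of 44 measured genes were higher and 1 lower. The higher genes were Sprr1b (184 and 899 FPKM), Rptn (31.6 and 123 FPKM) and 5 of the 6 Lce3 genes, with Lce3d at 6.39 and 46.5 FPKM and Lce3a at 0.825 and 9.08 FPKM. Over all 6 Lce3 genes the FPKM sum was 113 in WT and 272 in L19M, a ratio of 2.40. Lce3c, the most abundant of them and given after its values were seen, had 91.5 and 168 FPKM and was not called. The lower gene was Lce1m (3970 and 1897 FPKM), which was named after its values were seen. The list's median was -0.10 (percentile 29.4) and its mean 0.20, opposite in sign. The 14 Lce1 genes, which encode other envelope proteins, summed to 10449 FPKM in WT and 7213 FPKM in L19M. Also among the 15 largest log2 ratios were those of Spink7, a protease inhibitor gene (6.16 and 59.8 FPKM), and the noncoding RNA Bc1, listed at 0 in WT and 13.2 FPKM in L19M. Their transcripts of 258 and 146 bases are too short for a fragment estimate, and the Bc1 row spans 79697305 to 80369637 on chromosome 10, so its value is uncertain.

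In the basal and spinous keratinocyte lists no gene was called, unlike in the granular layer list. None of 20 measured basal keratinocyte genes met the 2-fold rule. Their median log2 ratio was 0.18 at percentile 100, with Trp63, the master regulator of stratified epithelium, at 55.5 FPKM in WT and 82.5 FPKM in L19M. Igfbp3 (0.58) was above 0, and Syt8 (-0.62) and Postn (-0.61) below. None of 23 spinous genes met the rule, and their median of -0.04 (percentile 66.4) changed sign under other settings. Skint3 (75.8 and 37.5 FPKM), Tmem45a (192 and 118 FPKM), Krt77 (64.8 and 41.7 FPKM) and Krtdap (18400 and 13729 FPKM) had the largest differences. Among 25 measured barrier lipid genes Fa2h, a fatty acid hydroxylase, was lower, at 15.3 FPKM in WT and 2.83 FPKM in L19M. That list's median was -0.20 at percentile 0.35, with Acer1 at -0.58, Degs2 at 0.56 and Asah1 at -0.41. In the list of NF-kappaB and keratinocyte transcription factors none of 33 measured genes was called, and the median was 0.22 (percentile 100). Hopx (0.57) and Nfkbia (0.54) lay above 0 and Gata6 (-0.66) below. Notch pathway genes had no call among 16 and a median of 0.09 (percentile 83.9), with Dtx3 (0.47), Maml1 (0.34), Heyl (-0.30) and Hes1 (0.20) furthest from 0.

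Genes of sebocytes, the lipid-filled cells of the sebaceous gland, were lower in L19M. Of 17 measured members 7 were at least 2-fold lower and none higher, and the median log2 ratio was -0.73 at percentile 0. Elovl3, a fatty acid elongase, had 13.8 FPKM in WT and a ratio of 0.181, with an interval of 0.140 to 0.231. The desaturase Scd1 had 36.1 and 13.2 FPKM and the wax ester synthase Awat1 13.7 and 4.88 FPKM. Cidea, a lipid droplet protein also in the adipocyte list, had 14.8 and 5.57 FPKM. The adipocyte list had 6 of 17 measured genes lower and none higher, with a median of -0.37 at percentile 0. The adipokine gene Retn (29.2 and 7.39 FPKM), Gpd1 (7.72 and 2.36 FPKM) and Car3 (22.7 and 9.51 FPKM) were lower with Cidea. Fabp4, the most abundant adipocyte gene of that list, had 307 FPKM in WT and 252 FPKM in L19M, and Adipoq had 15.5 and 7.95 FPKM. Both are given after their values were seen. Of the 17 adipocyte genes, 14 were below 0 and 3 above. Those 3 were Slc2a4 (0.25), Pnpla2 (0.01) and Cebpa (0.001), and Lipe (-0.04) and Cfd (-0.13) were among those below. These 5 are also given after their values were seen. Retn was also the 1 called gene of 24 measured in the list of other growth factors and adipogenic ligands. That list's median was 0.05 (percentile 77.2) and its mean -0.04, with Ereg (0.89), Insl6 (0.74) and Fgf22 (-0.83) next. None of 22 ligands and antagonists of the BMP and TGF-beta families was called. Their median was -0.01 and their mean 0.01 (percentile 39.9 for the median), the median's sign changed under other settings, and Inha (0.81), Id3 (0.42), Bmp4 (-0.39) and Id4 (-0.37) were furthest from 0.

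The medians of the fibroblast and adipocyte precursor, endothelial and muscle lists lay above 0, while that of the adipocyte list lay below. Even so, 6 of 25 measured fibroblast and adipocyte precursor genes and 5 of 16 muscle genes were below 0. No test compared the lists, and the share of such cells in each library was not separated from expression. None of 25 measured fibroblast and adipocyte precursor genes was called, and the median was 0.11 at percentile 99.4. Vim had 258 FPKM in WT and 423 FPKM in L19M, Lox 6.28 and 11.3 FPKM, Lum 46.7 and 29.6 FPKM, and Dpp4 10.3 and 5.85 FPKM. All 10 measured endothelial genes had log2 ratios above 0, with none called and a median of 0.46 at percentile 100. Plvap (0.82), Lyve1 (0.73), Esam (0.68) and Emcn (0.59) led them. Of 16 measured muscle genes Actc1, a striated muscle actin, was higher, at 3.70 and 11.1 FPKM. The median was 0.19 (percentile 99.7), with Myh3 (0.74), Tnnt1 (0.68) and Tagln (-0.53) next. Dermal papilla genes had no call among 7 and a median of 0.05 (percentile 59.4), with Sox18 (0.37), Inhba (-0.36), Wif1 (0.34) and Alx4 (-0.09) furthest from 0. Nerve, Schwann and Merkel cell genes had no call among 9 and a median of 0.04 (percentile 52.8) that changed sign under other settings. Krt8 (0.67) and Sox10 (0.61) were among those furthest from 0. The 2 measured erythroid genes, Hba-a1 (23.6 and 21.2 FPKM) and Bpgm (8.73 and 6.25 FPKM), had a median of -0.29 (percentile 7.63).

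The genes H2-Ab1, H2-Aa, H2-Eb1 and Cd74, of MHC class II molecules and their invariant chain, were lower in L19M. In the Langerhans cell and antigen presentation list, 5 of 20 measured genes were lower and none higher, with a median of -0.19 at percentile 0.32. Log2 ratios were below 0 for 15 members and above 0 for 5. Those 5, given after their values were seen, were Lyz2 (0.70), Aif1 (0.50), Cx3cr1 (0.39), Cd68 (0.30) and Itgam (0.13). Cd207, also given after, was not measured, with 5 estimated fragments in WT and 1 in L19M. H2-Ab1 had 50.8 FPKM in WT and 11.6 FPKM in L19M, H2-Aa 45.2 and 10.3 FPKM, H2-Eb1 17.5 and 4.39 FPKM, and Cd74 86.7 and 26.8 FPKM. The class II genes H2-DMa (5.01 and 3.95 FPKM) and H2-DMb1 (5.44 and 3.20 FPKM), given after their values were seen, were not called. The chemokine Ccl6, the other called gene, was named after its values were seen (34.6 and 13.1 FPKM). In the T cell list 1 of 9 measured genes was lower, Cd3g, a chain of the T cell receptor complex (13.9 and 4.81 FPKM). That list's median was -0.46 at percentile 0.02, with Ctsw (-0.76), Nkg7 (-0.74) and Cd7 (-0.74) next. Of its measured genes 6 were below 0 and 3 above. Those 3, given after their values were seen, were Thy1 (0.37), Lck (0.29) and Xcl1 (0.05). The share of immune cells in each library was not separated from expression. Interferon-stimulated genes had no call among 19 and a median of 0.22 (percentile 99.8), with Irf7 (-0.87), Isg15 (0.63), Oasl2 (0.55) and Irf1 (0.46) furthest from 0.

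Proliferation genes had lower values without any 2-fold call. Of 40 measured, 34 had log2 ratios below 0, and the median was -0.29 at percentile 0. Cenpf (6.77 and 3.30 FPKM), Cdk1 (18.9 and 10.2 FPKM), Bub1 (4.81 and 2.36 FPKM) and Top2a (33.3 and 19.8 FPKM) had the largest differences. Cholesterol synthesis genes had no call among 24, a median of 0.03 (percentile 83.5) and a mean of -0.03. Msmo1 (-0.72), Mvd (0.56), Fdft1 (-0.46) and Tm7sf2 (-0.40) were furthest from 0.

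Of the lists that describe sample handling and animals, only the sex-linked list held calls. Its 4 called genes are on the Y chromosome and were lower in L19M. Eif2s3y had 47.4 FPKM in WT and 0.200 FPKM in L19M. Ddx3y (18.0 FPKM in WT), Uty (3.92 FPKM) and Kdm5d (2.47 FPKM) had 1 estimated fragment each in L19M, with ratios of 0.000651 (interval 1.65e-05 to 0.00363), 0.00264 (interval 6.67e-05 to 0.0148) and 0.00401 (interval 0.000101 to 0.0226). Xist, which is transcribed from the inactive X chromosome of females, had 1.89 FPKM in WT and 4.50 FPKM in L19M. The remaining measured gene that the table places on the Y chromosome, Erdr1, was in no list and had 94.1 FPKM in WT and 95.9 FPKM in L19M. The median of the 5 measured sex-linked genes was -2.28 (percentile 0). Immediate early and heat shock genes had no call among 26 and a median of 0.06 (percentile 96.8), with Atf3 (0.78), Klf2 (0.65), Egr2 (-0.63) and Nr4a1 (0.63) furthest from 0. Clock genes had no call among 13, a median of -0.01 (percentile 34.9) that changed sign under other settings, and a mean of 0.03. Per1 (0.37), Nr1d1 (0.30), Nfil3 (-0.16) and Nr1d2 (0.16) led them. Ribosomal protein genes had no call among 79, and their median of -0.03 (percentile 96.4) changed sign under other settings. Rps27 (0.65), Rpl26 (-0.59), Rpl30 (-0.49) and Rps13 (0.27) were furthest from 0. The smallest log2 ratio of the named genes (-6.42) was that of Nme2, a nucleoside diphosphate kinase, with 829 FPKM in WT and 8.67 FPKM in L19M. Its neighbour and close paralog Nme1 had 141 FPKM in WT and 116 FPKM in L19M. How fragments shared by such genes were divided is not given in the sources used here, so the value of Nme2 is uncertain.

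**Figure D3:**
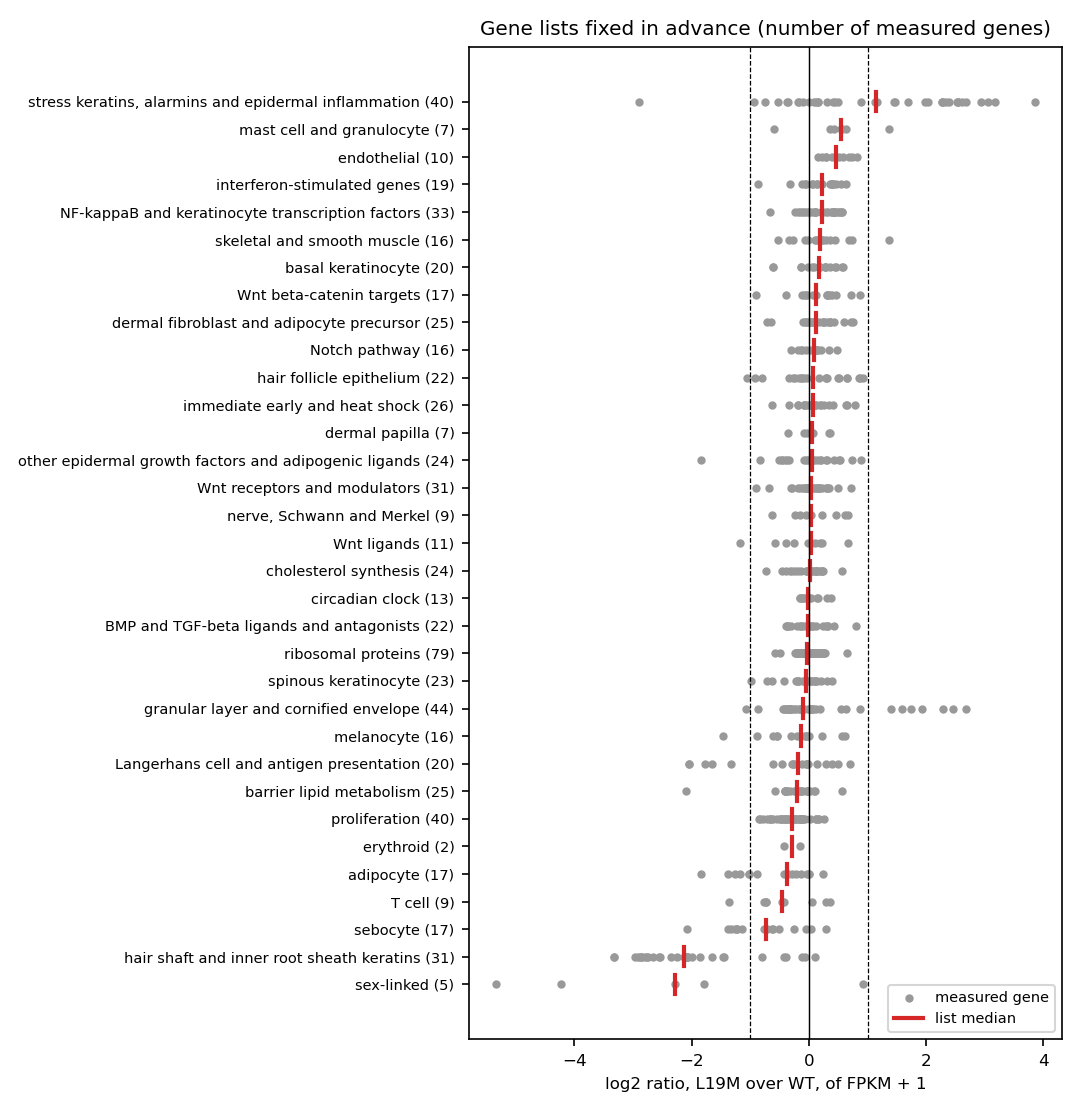
Log2 ratio of L19M over WT, of FPKM + 1, for each measured gene (grey points) of each list fixed before the data were examined, with the number of measured genes in parentheses and the list median in red. Dashed lines mark 2-fold. The hair shaft list has a median of -2.13, the sebocyte list -0.73 and the stress and alarmin list 1.14, and the sex-linked list (-2.28) holds 4 Y-linked genes and Xist.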

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

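No paired analysis was possible because there was 1 library per genotype and no test. The counts of called genes depended most on the pseudocount, the floor and the fold rule, each of which alters what can pass by construction. Against 63 genes at least 2-fold higher in L19M and 203 genes at least 2-fold lower in L19M, a pseudocount of 0.1 gave 120 higher and 297 lower, and a pseudocount of 0.01 gave 134 higher and 311 lower. A floor of 5 FPKM gave 41 higher and 107 lower. The 1.5-fold rule gave 236 higher and 482 lower, and the 4-fold rule 29 higher and 85 lower. Centring, library sizes without the 20 most abundant genes, no floor and the authors' quantile-normalized values kept both counts within 1.5 times, and with the last 63 higher and 201 lower genes were shared. Added after seeing the data were runs without transcripts under 300 bases (54 higher, 199 lower), without genes on X and Y (61 and 196) and with at least 40 estimated fragments over both libraries (44 and 173). Of 145 named genes none changed sign under any of 5 settings for scaling, pseudocount or the authors' values, Foxn1, Wnt5a and Wnt5b included. A pseudocount cannot alter a sign, and the other settings moved ratios little, so this stability follows largely by construction. It does not speak to variation between animals. With a pseudocount of 0.1, 15 named genes under 2-fold reached it. Of 33 list medians 7 changed sign under some setting, and the largest of these was 0.07 in size. The scaling that left out the 20 most abundant genes moved ratios by 0.05 on the log2 scale. TMM and DESeq2 size factors were not run, since they need counts, and summing rows by symbol was not run, since no symbol was repeated. Counting error limits genes with few fragments: of 54 higher genes with an interval, 53 excluded equality and 40 lay beyond 2-fold, and of 199 lower genes 197 and 171 did.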

Other observations

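The gene lists and single genes of this paragraph were chosen after their values were seen. Of 14 measured genes known to respond to glucocorticoids, 2 were at least 2-fold higher in L19M and 12 had log2 ratios above 0, with a median of 0.36. Fkbp5 had 10.7 FPKM in WT and 36.9 FPKM in L19M, and Zbtb16 had 0.561 and 2.85 FPKM. Cyp11a1, the enzyme of the first step of steroid synthesis, had 3.65 and 15.8 FPKM. Calca, the gene of calcitonin and a related neuropeptide, had 0.179 and 3.23 FPKM. Amd1 had 6.53 FPKM in WT and 0.0245 FPKM in L19M, beside 32.7 and 30.7 FPKM for the overlapping Amd2.

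Of the tests that follow, the one on pup age was set before its result was seen, and those on follicle cells, handling, neutrophils and sex were chosen after. Hair shaft and inner root sheath genes had a median log2 ratio of -2.13 in L19M. Fewer follicle cells in the L19M sheet would lower other follicle genes about as much. The 22 measured genes of the hair follicle epithelium list had a median of 0.069, with quartiles of -0.22 and 0.51. Their lowest value was -1.06, against an upper quartile of -1.56 for the shaft list. Of the 22, 11 were above 0, among them Lef1 (0.87), Edar (0.65) and Shh (0.51). The other 11 were below, among them Krt79 (-1.06), Foxe1 (-0.92) and Tbx1 (-0.80). This argues against an equal loss of all follicle cells as the whole cause, as far as the list tracks those cells. It is not confined to them, since Krt17 is also in the stress list, and a loss of some follicle cells is not decided. Younger L19M pups, whose follicles may not yet make shaft, cannot be told apart from the genotype, and the labels give no day of age. Age was not separated from genotype for any other gene or list either, the sebocyte, adipocyte, antigen presentation and T cell lists included. Genes that decline after birth had a median of 0.24, at percentile 99.95 of matched random lists, with 78.6% higher. The median was short of the 0.3 set in advance, but its direction was that of younger L19M pups. That direction was not particular to this list. The medians of the endothelial (0.46), muscle (0.19) and fibroblast and adipocyte precursor (0.11) lists were also above 0. A role of the Foxn1 allele in shaft differentiation stays open as a hypothesis that 1 library per genotype cannot test.

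The stress and alarmin list had a median log2 ratio of 1.14. Rough handling or delay shortly before RNA extraction would raise immediate early genes. Their median over 14 measured genes was 0.10, with an upper quartile of 0.31, at percentile 96.65 of matched random lists. That shift is small beside 1.14, but it does not speak to handling earlier or longer than these genes would record. Handling is therefore not decided as a cause. For S100a8 and S100a9 a neutrophil share cannot be told apart from keratinocyte expression: the neutrophil receptor gene Cxcr2 had a ratio of 2.17 (interval 1.47 to 3.28) and Csf3r 2.35 (interval 1.19 to 4.91), against 6.00 (interval 4.63 to 7.87) for S100a8, while Ltf had 6 estimated fragments in WT and 0 in L19M (upper bound of the ratio 0.627), Ngp and Retnlg each had 2 and 7, and Camp, Elane and Mpo had none in either library. An altered state of the L19M keratinocytes, from the allele, age, litter, housing or handling, may remain, and these were not separated.

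The 4 Y-linked genes of the sex-linked list were at most 0.422% of their WT FPKM in L19M, unlike Erdr1, which the table also places on Y and which had similar FPKM in both libraries (94.1 and 95.9). A candidate explanation, written after the Xist values were seen, is that WT RNA came from pups of both sexes and L19M RNA from females only. Xist in WT would then lie between none and all of the L19M level. The ratio was 0.419, with a counting interval of 0.369 to 0.476, which is not an independent check. If so, genotype and sex are partly confounded in these libraries. Without genes on X and Y the counts were 61 higher and 196 lower, but an effect of sex on other genes was not tested.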
